A study of Arabidopsis thaliana with 4 samples.

How the data were processed

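RNA from whole Arabidopsis thaliana plants was measured on 4 single-colour Affymetrix arrays, 2 of ppi2 plants grown for 20 days and 2 of wild-type plants grown for 10 days, per the labels. The ppi2 mutant carries a T-DNA insertion in TOC159, a receptor for protein import into chloroplasts. Group and replicate number were taken from the sample titles. The labels call the 2 arrays of a group biological replicates but do not say whether plants were grown in separate batches, so p-values measure only the spread between these arrays. Genotype and age changed together and could not be separated.

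The values deposited by the authors were probe-set signal intensities on a linear scale, made with MAS5, the only tool named in the submitters' processing notes; its version and scaling target are not given in the sources used here. Without control probe sets, each array's 2% trimmed mean lay within 0.41% of the others, so no further scaling was applied. With the controls it was 500 on every array. No detection calls were used. The number of arrays limits the precision of every value.

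The table held 22810 probe sets, of which 64 were controls and were left out of the tests. A platform annotation table listed 14016 probe sets, 13513 with 1 gene and 503 with several, and the other 8794 had no name here. Of the probe sets with 1 gene, 13436 were matched by gene identifier to a RefSeq gene table of assembly TAIR10.1, used only for names, chromosomes and neighbouring genes. Probe sets with several genes were tested but never named. No probe set was assigned to TOC159, to the ubiquitin ligase CHIP or to the heat shock gene AT3G12580, so the mutated gene could not be used to check the labels. The list of plastid genome genes was fixed by an identifier prefix that the gene table did not use, and was taken as the genes it places on the plastid chromosome.

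A pseudocount of 7.99, the 10th percentile of all signals, was added before taking log2, so differences of dim probe sets are understated. The brightest probe set stood for each gene, which removed 157 others, and probe sets with a mean signal under 124, the 40th percentile, were left out (8985), leaving 13604. The labelled groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, group as the only term, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with 2 residual and 2.59 prior degrees of freedom. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. The test, the 27 gene lists and the rule for named genes were fixed before the data were examined. The rule took TOC159, cytosolic HSC70 family members and CHIP, up to 24 genes past the threshold with the largest differences whose group ranges did not overlap, and up to 4 members of each list past the threshold or otherwise the 2 with the smallest p.

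Because the arrays did not group by label, differences between the array labelled ppi2 and the array labelled wild type were also taken within each replicate number. This description was chosen after the data were seen. Each such difference rests on 1 array per arm, so it has no error and no p-value. To say whether a list stood apart, its median was placed among the medians of 10000 random lists of the same size. These were drawn gene by gene from 20 bins of mean expression. Genes regulated together were not allowed for, which can make the percentiles too extreme. Intervals of list medians came from 2000 bootstrap draws of the members. Other genes were named by their values: the 12 named genes in each direction with the largest smaller difference of both numbers, among those at or above the median mean signal, and examples of the groups described.

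The steps were tested on simulated tables of 13604 probe sets with 200 changed ones. Another 30 formed a list shifted by 1 on the log2 scale. Noise was independent and of the same size for every probe set. In the comparison of ppi2 with wild type, at the noise of the closest pair of arrays (SD 0.21 on the log2 scale), limma recovered 96% of the changes of 1 on the log2 scale and 100% of those of 2. At the noise of the labelled groups (SD 0.668) it recovered 0% of changes of 1, 24% of 2, 80% of 3 and 98% of 4. With the labels of replicate 2 exchanged it recovered 0% at every size and at both noise levels. This outcome was fixed in advance, since the changes then cancel between the labelled groups, and says nothing about these arrays. The alternatives were quantile normalization, median centring, other pseudocounts, filters and variance models, the replicate number as a block, leaving out each array, an estimated correlation and fry in place of camera, and keeping shared probe sets in the lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.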

Results

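The series compared plants lacking the chloroplast import receptor TOC159 (ppi2) with wild-type plants, on 4 arrays with 2 per group. The question known for the study is how cells handle plastid precursor proteins that are not imported, through the cytosolic chaperone Hsc70, the ubiquitin ligase CHIP and the proteasome. Median signals were similar on all arrays, at 193 and 201 on those labelled ppi2 replicates 1 and 2 and 213 and 199 on those labelled wild type replicates 1 and 2. Arrays are named throughout by their labels, which could not be checked by the TOC159 signal.

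Photosynthesis genes did not separate the labelled groups. LHCB4.2 (AT3G08940), an antenna protein of photosystem II, had signals of 841 and 29460 on the arrays labelled ppi2 replicates 1 and 2, and of 30100 and 714 on those labelled wild type replicates 1 and 2. PORB, an enzyme of chlorophyll synthesis, gave 2894 and 19750 against 26440 and 2516. The reverse crossed order was seen for AT3G09440, a cytosolic Hsc70, with 2953 and 1023 against 680 and 3518. Over all 13604 tested probe sets, ppi2 replicate 1 correlated best with wild type replicate 2 (r = 0.981) and ppi2 replicate 2 with wild type replicate 1 (r = 0.953), across genes, which are not independent replicates. The other 4 of the 6 pairs of arrays, including the replicates of each group, had r between 0.798 and 0.823.

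Between the labelled groups, 0 probe sets passed the threshold in the limma fit, and 0 did so with a 2-fold difference. At an unadjusted p under 0.05 there were 8 probe sets, where uniform p-values would give 680, and the smallest unadjusted p was 0.0231 (limma). GER2, named after its value was seen, was among these 8, with 336 and 380 against 214 and 195, a log2 difference of 0.78. AT3G51270, chosen in the same way, had 189 and 173 against 331 and 347, a log2 difference of -0.88. The labelled log2 differences of the 37 genes named by rule lay between -0.43 (LHCB4.3) and 0.71 (ndhE), and none passed, either over all probe sets or adjusted over the list alone. The median standard error of a labelled difference was 0.376. The contrast of ppi2 replicate 1 and wild type replicate 2 with the other arrays held 84.1% of the sum of squares between arrays. That contrast, chosen after the data were seen, counted as residual spread in this fit, so the p-values could not be uniform. The low counts thus do not show that ppi2 had no effect.

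**Figure D1:**
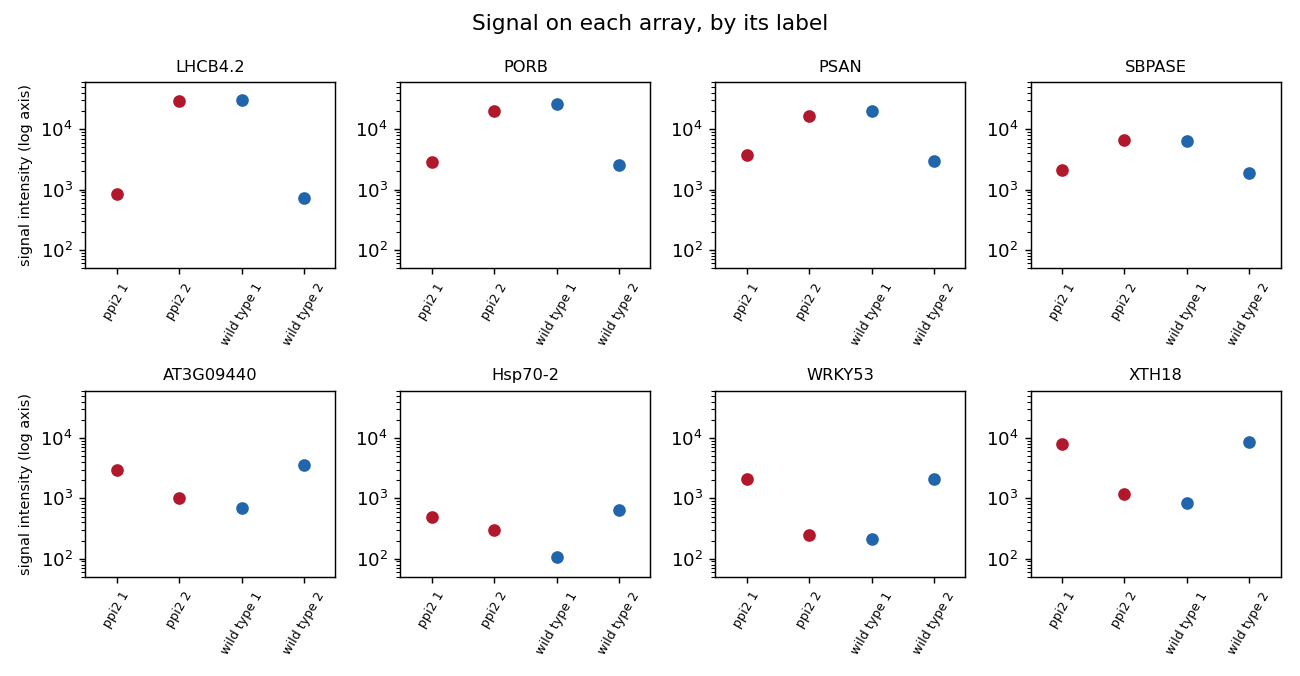
Signal intensity (log axis) of 8 genes on each of the 4 arrays, 1 point per array, red for arrays labelled ppi2 and blue for those labelled wild type. For LHCB4.2 the arrays labelled ppi2 replicate 1 and wild type replicate 2 read 841 and 714, and the other two read 29460 and 30100.

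Of the 5 gene lists tested between the labelled groups with camera, 0 passed the threshold. Plastid genome genes came nearest (63 members, median 0.10 higher in ppi2, limma camera adjusted p = 0.0937), with adjusted p = 0.997 with an estimated correlation and 0.997 with fry. With the replicate number as a block this list passed, at a camera adjusted p of 0.0119, and with shared probe sets kept it passed at 0.035. With an estimated correlation these became adjusted p = 0.993 and adjusted p = 0.997 (limma camera). That correlation comes from the residual spread, which has few degrees of freedom. The spread mostly holds the contrast of ppi2 replicate 1 and wild type replicate 2 with the other arrays. Lists whose members move along that contrast can hardly pass, so these values do not decide whether the calls hold. Photosystem subunits (median 0.04), chlorophyll synthesis enzymes (-0.10), cytosolic Hsp70 chaperones and partners (0.04) and proteasome subunits (-0.01) each had a camera adjusted p of 0.993. The chaperones had a positive median while camera placed them below the other genes. Each array was also left out. The photosystem subunits had a median of 0.88 without ppi2 replicate 1 and -0.85 without ppi2 replicate 2. It was 0.91 without wild type replicate 1 and -0.85 without wild type replicate 2. These fits leave 1 array in a group, so only the medians are given.

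Within replicate number 1, the tested nuclear genes of photosynthesis were lower on the array labelled ppi2, and within replicate number 2 they were higher on it. Few fixed members could be tested. These were 5 of 30 photosystem and electron transport subunits and 6 of 22 enzymes of chlorophyll and heme synthesis. Of the antenna proteins 3 of 18 were tested, and of the Calvin cycle enzymes 4 of 20. All 5 tested photosystem and electron transport subunits were at least 2-fold lower in the first and at least 2-fold higher in the second, with median log2 differences of -1.71 and 1.74, at percentiles 0.2 and 99.85 of matched random lists. PSAN, a photosystem I subunit, read 3737 and 16910 against 20120 and 2975. Of 6 enzymes of chlorophyll and heme synthesis, 5 were lower in the first and higher in the second and 1, HEMA2, was the other way round (1059 and 370 against 395 and 796). Their medians were -1.53 and 1.43, at percentiles 0.05 and 99.93, with 95% bootstrap intervals over members of -2.46 to 0.40 and -0.34 to 2.31, both including 0. The 3 antenna proteins, all forms of LHCB4, had medians of -2.08 and 1.77, with LHCB4.3 at -0.884 and 0.026. The 4 Calvin cycle enzymes had medians of -1.48 and 1.63, with SBPASE at 2133 and 6577 against 6466 and 1880. After quantile normalization the antenna medians were -1.24 and 1.12, and those of the Calvin cycle enzymes -1.42 and 1.61. These differences rest on 1 array per arm and were not tested.

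The genes of the plastid genome had a median of -0.72 in replicate 1 and 0.99 in replicate 2, at percentiles 0 and 100 (-0.47 in replicate 1 after quantile normalization), and split by gene class. Of the 63, 44 were lower then higher, 15 higher then lower and 4 had the same sign in both. Among 39 genes of photosynthesis (named psa, psb, pet, atp, ndh or rbcL), 37 were lower then higher and 0 higher then lower, with medians of -0.98 and 1.32. Among 17 genes of transcription and translation (rpo, rps and rpl), 13 were higher then lower and 4 lower then higher, with medians of 0.64 and -0.33. The RNA polymerase gene rpoC2 read 1394 and 481 against 269 and 2169, and rps4, for a ribosomal protein, 20850 and 7922 against 5653 and 21290, while psaA, of the photosystem I core, read 219 and 5834 against 1370 and 695. The remaining 7 genes had medians of 0.02 and 0.45, with 3 lower then higher. The other way went 2, including the protease gene clpP (12030 and 9312 against 3487 and 12470). The same sign in both was seen for 2, including accD (185 and 425.5 against 92.5 and 310), higher in both. Grouping by name was chosen after the values were seen. Whether these signals follow the amounts of plastid RNA was not tested. Signs of both class medians were the same after quantile normalization and median centring. With quantile normalization the medians were 0.70 and -0.535 for transcription and translation, and -0.87 and 1.16 for photosynthesis.

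**Figure D2:**
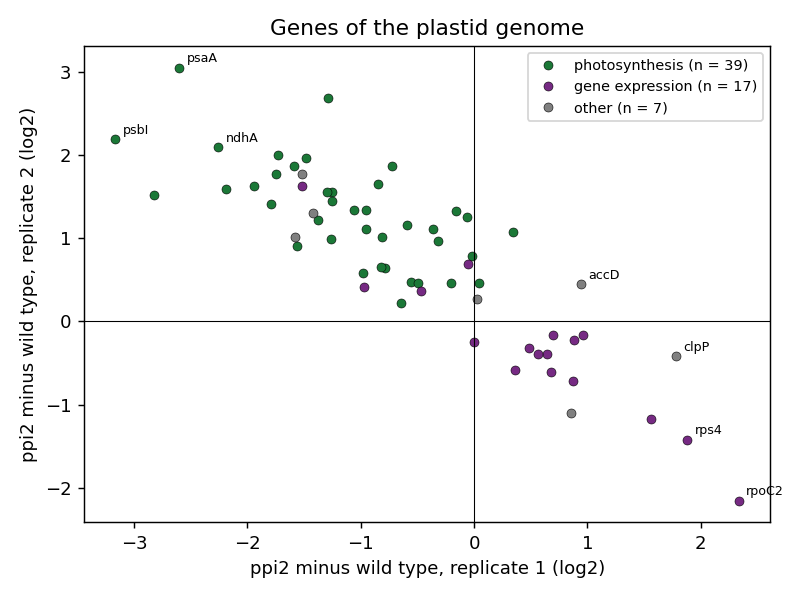
Log2 difference of the array labelled ppi2 from that labelled wild type in replicate 1 (x axis) and replicate 2 (y axis), 1 point per plastid genome gene, coloured by name class. Of the 39 photosynthesis genes, 37 lie in the upper left, and 13 of the 17 genes of transcription and translation lie in the lower right.

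Cytosolic chaperones ran opposite to the photosynthesis genes. The 7 tested members of the Hsp70 and Hsp90 list were Hsp70-2, AT3G09440, Hop1, Hop2, Hop3, Fes1A and AT5G48570, so no Hsp90 gene was tested. Of these 7, 6 were higher in replicate 1 and lower in replicate 2, 4 of them at least 2-fold in both. The medians of the 7 were 1.21 and -1.10, at percentiles 99.96 and 0.1. With the filter at the 60th percentile 5 members remained, with medians of 0.41 and -0.79. Hsp70-2, a cytosolic Hsc70, read 493 and 297 against 109 and 647. Hop2, a co-chaperone, differed least within replicate 1 (1238 against 1232). Of 9 proteasome subunits, 7 were higher then lower, with medians of 0.36 and -0.21 at percentiles 85.11 and 30.4, which did not stand apart from random lists. CHIP had no assigned probe set, so its level was not analysed here.

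Genes of senescence and sugar starvation (3 members, medians 1.502 and -1.901) and of oxidative and mitochondrial stress (3 members, 1.56 and -0.76) were higher then lower in every tested member. SAG101, of leaf senescence, read 513 and 163 against 176 and 632, and AT2G21640, of the oxidative stress list, 581 and 115 against 109 and 906. Photorespiration enzymes had medians of -0.82 and 0.80 (3 members), plastid ribosomal proteins of nuclear genes -0.33 and 0.63 (4), plastid fatty acid enzymes -0.11 and -0.03 (4), plastid isoprenoid enzymes -0.17 and 0.20 (2) and plastid chaperones and proteases -0.05 and 0.22 (3). Antioxidant enzymes had medians of 0.06 and 0.49 (2 members) and epidermal markers -0.09 and 0.49 (2). Single members stood for the import machinery (SPP, -0.71 and 0.12), cell division (AUR1, -0.81 and 0.72), shoot age (AGL24, -0.05 and -0.19) and roots (EXPA18, -0.57 and 0.42). Small median differences changed sign with the scaling: fatty acid enzymes in replicate 2 with median centring, and antioxidant enzymes and shoot age in replicate 1 with quantile normalization. No member was tested for 7 lists, those of plastid sigma factors and regulators, small heat shock proteins, endoplasmic reticulum chaperones, flavonoid synthesis, salicylate defence, jasmonate and seed storage.

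Over all tested probe sets the differences of the replicate numbers were opposite. A 2-fold difference in both was seen for 1759 probe sets, of which 972 were lower then higher, 783 higher then lower, 1 lower in both and 3 higher in both. The correlation of both differences across probe sets was -0.839 (Spearman -0.764). Without the signal filter it was -0.49, with 2988 probe sets opposite and 643 in the same direction at 2-fold. With the filter, the 2 named genes with the same direction, AT5G40020 (136 and 288 against 25.7 and 101) and AT3G03680 (183 and 240 against 85.6 and 114), were dim. Spiked poly-A controls (24 probe sets) were 4-fold brighter on both replicate 1 arrays. Hybridisation controls (18 probe sets) had median signals of 840 and 1669 on the ppi2 arrays and 1514 and 1106 on the wild type arrays, thus lower on the arrays where the photosynthesis genes were lower. The actin 3' to 5' signal ratio was 38.8 and 26.8 against 34.0 and 30.7, and that of GAPDH 1.63 and 1.96 against 2.62 and 1.92.

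**Figure D3:**
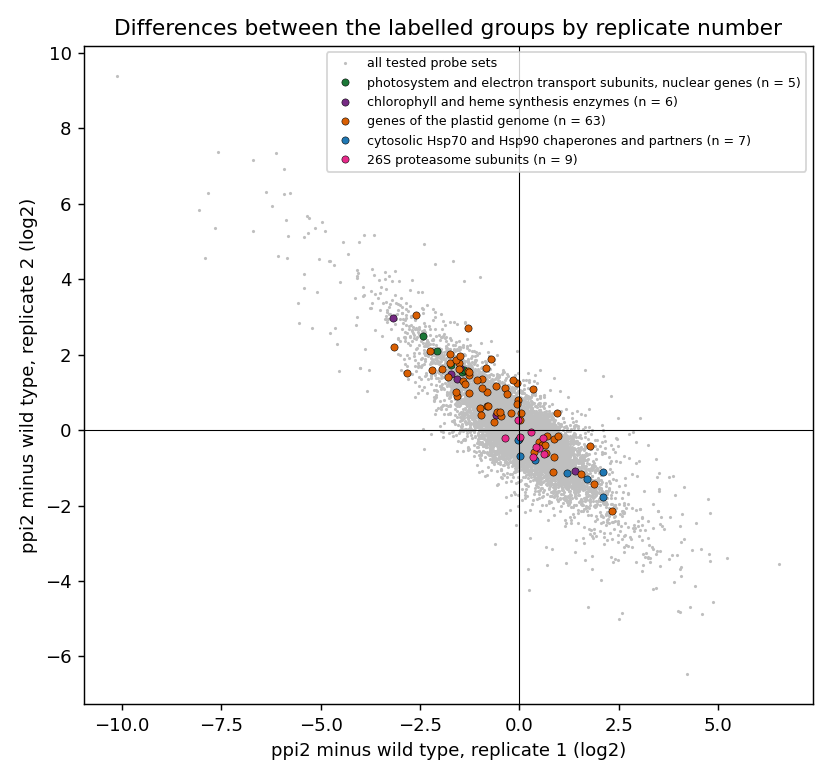
Log2 difference of the array labelled ppi2 from that labelled wild type in replicate 1 (x axis) and replicate 2 (y axis), 1 grey point per tested probe set (13604), with members of the 5 tested lists in colour. Points follow a falling diagonal, with a correlation of -0.839 across probe sets.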

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

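The tests in this part, on differences within a replicate number and on shares of the sum of squares, were chosen after the opposite differences had been seen. For 4 gene lists the difference between the arrays labelled ppi2 and wild type pointed one way in replicate 1 and the other way in replicate 2, outside the central 95% of matched random lists in both. They included photosystem and electron transport subunits (median log2 -1.713 and 1.738), plastid genome genes (-0.722 and 0.994) and cytosolic Hsp70 chaperones and partners (1.211 and -1.101). The last list was chlorophyll and heme synthesis enzymes (-1.531 and 1.429, with bootstrap intervals over members that include 0 in both). With 1 array per arm, the difference between the replicate numbers was not tested. The differences of both numbers correlate at -0.839 over all probe sets, so the percentile in replicate 2 is no separate evidence. Random lists drawn gene by gene also ignore shared regulation within a list, which can make percentiles too extreme.

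The opposite signs themselves exclude a labelled difference of genotype and age common to both replicate numbers as the whole cause; its share of the sum of squares between arrays, 7.47%, restates them and is no separate test. A batch common to both arrays of a replicate number, as the poly-A controls showed, cancels in these differences, and its contrast held 8.45%. Array-wide brightness would have been removed by quantile normalization, but the correlation of both differences was then -0.834. That the 2 arrays of one replicate number carry each other's label or values is a candidate explanation that was not tested: the correlation of -0.839 and the crossed best partners are the pattern itself, and with no probe set assigned to TOC159 in the annotation used, no independent value was at hand. It cannot be told apart from growth or greening that differed between cultures, which also stays open.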

How the results depend on the processing

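Among the alternatives, the estimated correlation combined with another setting, the crossed replicate numbers and all settings applied to differences within a replicate number were chosen after the data were seen. The count of probe sets past the threshold was 0 under every alternative run, also with a 2-fold difference, including the fit with the replicate number as a block. The numbers did not pair the arrays (correlation of same-numbered deviations -0.818), and with crossed numbers as a block the count was 0. Of 474 values of the 37 named genes, 0 passed the threshold and 48 had the other sign. Gene lists past the threshold were 0 in the main analysis and 1 with the replicate block (plastid genome, camera adjusted p = 0.0119, the only list call the block changed) and 1 with shared probe sets kept (plastid genome, median 0.127, adjusted p = 0.035), which became adjusted p = 0.993 and adjusted p = 0.997 with an estimated correlation. Leaving out 1 array gave 1 to 3 lists, where the lone array is assumed to vary like the other group; 0 of these 10 calls passed with an estimated correlation (adjusted p from 0.251 to 0.865). The shifts then ranged from -0.85 to 0.912 for photosystem subunits, from -0.597 to 0.73 for plastid genome genes, from -0.754 to 0.69 for chlorophyll enzymes and from -0.571 to 0.845 for cytosolic chaperones: signs followed which array was left out. Without a filter the correlation of both differences was -0.49, with 2988 probe sets opposite and 643 in the same direction at 2-fold, since dim probe sets enter. The same-direction count of 4 became 2 with quantile normalization, 2 with the pseudocount at the 25th percentile and 0 with the filter at the 60th. Quantile normalization gave photosystem medians of -1.264 and 1.346; the cause was not tested. No list median within a replicate number changed sign among the 5 tested lists, but that of cytosolic chaperones in replicate 1 was 0.407 with the filter at the 60th percentile, which left 5 members, and that of plastid genome genes -0.474 with quantile normalization. The TOC159 level was not run, since no probe set was assigned to it in the annotation used. Signal near the floor, with no detection calls, limits what dim probe sets show.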

Other observations

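All groups, examples and tests in this part were chosen after the data were seen. Of 18 xyloglucan hydrolases and expansins, 9 were lower then higher, 3 of them at least 2-fold, and 9 higher then lower, 4 of them at least 2-fold. The group median did not stand apart from random lists (medians 0.06 and 0.04, percentiles 60.06 and 67.94). With members going both ways, a median near 0 does not show that they were unchanged. XTH18, a xyloglucan-modifying enzyme, read 7900 and 1162 on the arrays labelled ppi2 against 826 and 8568 on those labelled wild type, and the expansin-like EXLA1 13820 and 2368 against 2470 and 13310. The expansin EXPA8 ran the other way (216 and 1842 against 1394 and 315). The pectin methylesterase gene ATPMEPCRB read 2523 and 225 against 259 and 2375. WRKY53, a transcription factor of senescence and defence, read 2100 and 245 against 209 and 2087. COR15A and COR15B, cold-regulated chloroplast proteins, read 95.3 and 3609 against 3243 and 70.9, and 98.3 and 4158 against 4162 and 77.0. The auxin response gene IAA29 read 92.2 and 1051 against 856 and 129. In the autophagy family ATG8B (645 and 241 against 200 and 692) and ATG8C (503 and 1158 against 1494 and 432) were opposite.

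Of 25 groups defined by gene names, 14 had at least 5 tested members, and 2 lay outside the central 95% of matched random lists in both replicate numbers. Lying outside in both is 1 observation, since both differences are correlated. These groups were 9 genes of the chloroplast NDH complex and thylakoid (medians -1.334 and 1.497) and 5 named photosystem and antenna genes (-2.07 and 1.77). The latter overlap the fixed lists, and their medians were -1.236 and 1.346 after quantile normalization. The name patterns of cytochromes P450 and sugar genes were narrowed after they had caught genes of other families. In the NDH group, NdhS read 1177 and 4303 against 3971 and 1460. The other 12, among them WRKY factors, glutathione S-transferases, cytochromes P450, expansins, autophagy genes, histones and cold-regulated genes, did not.

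Plastid genes of photosynthesis and of gene expression lay on opposite sides within each replicate number. The rpo, rps and rpl genes had a median of 0.641 in replicate 1 (95% bootstrap interval over genes 0.003 to 0.885) and -0.325 in replicate 2 (-0.604 to -0.162), with 4 of 17 the other way, and the photosynthesis genes -0.981 and 1.323. A different share of plastid RNA would move both classes to 1 side if plastid probe-set signals follow RNA amounts, which was not tested. On that condition these values argue against a different share as the whole cause. However, the classes were chosen from these data, plastid genes share transcripts and the first interval only just excludes 0. A candidate explanation is a different use of the plastid's own and the nuclear-encoded RNA polymerases, which are known to favour different plastid genes; it was not tested, since transcription itself was not measured.

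Some probe sets were near the floor on 2 arrays and bright on the other 2. Of 29 probe sets under 50 on 2 arrays and at least 400 on the others, 27 were low on ppi2 replicate 1 and wild type replicate 2, 2 on the other two, and 0 along the labels or the replicate numbers. Named ones include ECS1 (4.52 and 17170 against 13920 and 17.6) and QQS (1.56 and 1399 against 996 and 1.90), and the 15 named ones low on the first side lay on 5 chromosomes. All 15 lay on nuclear chromosomes, so these named ones are not plastid genome genes. The probe sets without a name were not covered, and nuclear genes for plastid proteins were not tested beyond the fixed lists. A strain variant against the array's sequence may contribute, but the test did not settle it. Against other opposite probe sets past the smallest difference that the limits allow, the share low on that side was 93.1% against 64.7% (Fisher's exact test, two-sided, p = 0.00261), 95.7% against 64.6% with limits of 100 and 800 (p = 0.00223) and 75% against 68.6% with limits of 25 and 200 (p = 0.544). Sizes were only partly matched: 24 of the 29 lay above a log2 difference of 4, where 14 of the 19 others were low on that side. Loss of expression would give the same signals and the labels name no strain, so both stay open.

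AT4G02540, 1 of these 15, read 47.1 and 1210 against 1528 and 46.9 and is separated from TOC159 by 2 genes in the gene table. It was picked after the values were seen, and whether its position bears on its signal was not tested.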
